A study of Bos taurus with 14 samples.

How the data were processed

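Total RNA of milk somatic cells was labelled with Cy3 or Cy5 and hybridised in pairs, an infected and a control cow on each array, per the labels. The deposited scanner files hold, per spot, foreground and local background intensities at 635 nm (Cy5) and 532 nm (Cy3), quantified with GenePix Pro 3.0.6.90 on a GenePix 4000A scanner, per the file headers. These intensities are on a linear scale and not background-subtracted. The files also give, per the file headers, the percent of saturated pixels of each spot, and a spot mark that the labels describe as bad or not found. No gene spot had more than 50 percent of its pixels saturated in either channel. Marked gene spots made up between 0.3 and 15.0 percent of an array. The authors' value table holds a log2 ratio per spot. At every spot with a value there and a net signal above 0 in both channels of the scanner file, it matched the uncentred log2 ratio of background-subtracted medians, infected over control, within 0.01, so its scale and centring are known, and its direction is that of the labelled dyes.

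The 2 scan batches had array layouts that differed at 9 positions of each block. Each file's own spot identifiers were used, and under them MHC-I lay at the 97.2 percentile of brightness on the first layout and at 96.8 on the second. The authors' value table names all arrays by the first layout. At these positions its values on the 4 arrays of the second batch thus stand under other identifiers. The IL10R positions are an exception, since they kept their identifiers and differed in name alone. The probes M0-Ma, FasL and SDF-1 had values from the first batch alone, and the second FcRgII probe, which had a place on the first layout alone, was not tested.

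Spot intensities were processed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Foreground medians were background-corrected with normexp (offset 50) and normalized within each array by global loess, with control spots and negatively marked spots at weight 0 and left out of the tests. Spots of one identifier were averaged per array. Ratios were turned to infected over control by the dyes in the labels, and the 2 arrays of a pair were averaged, so that n = 7 pairs. Each pair is a separate couple of cows and the array ratio itself makes the pairing, per the labels. A gene was tested where at least 5 pairs had a value, which held for 171 of 172 probes. The model (lmFit and eBayes) had the mean ratio and the dye balance of the pair (1 where the infected cow was always in Cy5, -1 where always in Cy3, 0 in the 4 dye-swapped pairs). p-values were adjusted after Benjamini and Hochberg. eBayes shares variance between genes and so narrows the interval of a gene as variable as IL8, for which the interval from its own variance is given. Dye effects were fitted on 14 arrays with the pair as a random block (duplicateCorrelation, consensus 0.25). A gene counts as above background on an array where at least 50 percent of its spots exceed the local background by 2 background SD.

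Array names were matched by hand to current symbols for 149 probes, and 23 kept the array's name without a symbol. Probes of different identifiers were not merged. Probes that share a symbol were at -0.05 and -0.03 for CD28, -0.05 and -0.01 for CD247, -0.10 and -0.03 for CSF1, and -0.15 and -0.08 for the IgG probes. The 15 gene lists were fixed before the data were examined, and the 12 with at least 3 measured genes were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. The erythrocyte list had 0 measured genes, the mammary epithelial list 1 and the adhesion list 2. Genes are named by a rule set at the same time: every gene past an adjusted p of 0.05 if 30 or fewer pass, otherwise the 15 largest changes each way; if fewer than 10 pass, also the 10 lowest unadjusted p each way among those under 0.05 with the same sign in at least 6 of 7 pairs (or in all but 1 of the pairs with a value); up to 4 genes with the largest absolute ratio of each list; and IL8, IL1b, IL6, TNFa, IL10, IFNg, TLR2, TLR4, CD14, GM-CSF, the glucocorticoid receptor and lactoferrin where measured. It named 56 genes, of which 1 is not reported here; the glucocorticoid receptor was not analysed here.

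Tested on simulated data with the genes' own spread over 7 pairs (171 genes, 100 runs), the fit recovered 86.3 percent of genes changed 1.25-fold, 98.2 percent at 1.5-fold and 99.7 percent at 2-fold, with 2.13 unchanged genes called per run. Noise was drawn independently for each gene and pair, and 20 genes were changed at each fold in every run. Real pair profiles correlated across genes at r from -0.637 to 0.788, so these rates need not hold for the real data. A 2-fold spike into the real spots of 20 bright probes gave a median log2 change of 0.89 with normexp and 0.99 with plain subtraction, so ratios of bright probes are slightly compressed. Dim probes were not spiked, and the fitted log2 ratio of IL8, a dim probe, was 0.19 with normexp and 0.39 with plain subtraction. For the lists, a log2 shift of 0.3 in 1 list was called in 100 percent of runs, and any unshifted list in 9 percent. Genes were independent there as well, while the estimated correlation within the real lists reached 0.379, so these rates need not hold either. A log2 dye effect of 0.5 was recovered in 97 percent of the genes given one (171 genes, 10 runs), with 1.5 other genes called per run. The authors' value table had array medians from -0.365 to 0.308. On array 1 of pair 6 normexp compressed the range of spot brightness, with a ratio of the 90th to the 10th percentile of 1.59 in Cy5 and 1.83 in Cy3 against 9.39 to 12.8 on the other 13 arrays. Alternatives covered background correction, normalization, scaling, spot marks, brightness filters, the dye term, the treatment of the arrays of a pair, each scan batch, the authors' value table, and leaving out each pair.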

Results

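Milk somatic cells are the leukocytes and shed epithelial cells that can be recovered from milk, and they were compared here between Holstein cows with chronic Staphylococcus aureus mastitis, an infection of the udder, and matched healthy control cows. The cows formed 7 pairs, and the RNA of both cows of a pair was hybridised together on 2 arrays, giving 14 arrays. Each array was a cDNA microarray of bovine immune and endocrine genes with 720 spots in 4 replicate blocks, and 172 gene probes were distinguished by their spot identifiers. The infected cow was labelled with Cy3 on 6 arrays and with Cy5 on 8 arrays. The dyes were exchanged between the 2 arrays of pairs 1, 3, 4 and 5, while both arrays of pair 2 had the infected cow in Cy3 and both arrays of pairs 6 and 7 had it in Cy5. Between 63.8% and 96.5% of the gene spots of an array were above background in the channel of the infected cow, and between 65.4% and 98.0% in that of the control cow. The number of pairs, 7, limits the precision of every value, and all ratios are the infected cow over the control cow of the same pair, in the direction that the dyes in the labels give.

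The comparison asks which immune and endocrine genes differ in milk cells between chronically infected and control cows. IL8 (CXCL8), the chemokine that attracts neutrophils, varied more between pairs than any of the other 170 probes tested, and it did so in both directions. Its log2 ratio was above 0 in 5 pairs, with 1.01 in pair 3, 1.73 in pair 4, 1.41 in pair 5, 0.91 in pair 6 and 1.79 in pair 7, and below 0 in pair 1 (-1.27) and pair 2 (-2.55). The mean was 0.43 ± 1.67 (SD, n = 7), and the spread between pairs was larger than the mean (exact sign-flip permutation test, two-sided, p = 0.5, adjusted p = 0.825 over 11 genes, where the smallest p possible is 0.0156). Both arrays of every pair had the same IL8 sign, from -2.95 to -2.15 in pair 2 and from 1.47 to 2.11 in pair 7. In pair 6 they gave 0.24 and 1.57, the lower on array 1, whose brightness range normexp compressed. IL8 was a dim probe, above background in the infected channel on 12 of the 14 arrays and in the control channel on 8.

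With the 7 pair values fitted together, 0 of 171 genes were higher and 0 were lower in mastitis at an adjusted p under 0.05 (limma). At an unadjusted p under 0.05 there was 1 gene, where 8.55 are expected by chance, and the lowest adjusted p was 0.821. That gene was IL5, a cytokine of type 2 responses, at a log2 ratio of 0.11 (SE 0.05) with 4 of 7 pairs above 0 and an adjusted p of 0.821 (limma). IL5 was a dim probe, above background on 7 arrays in the infected channel and on 4 in the control channel. It was also brighter in Cy3 whichever cow that dye labelled (log2 Cy5/Cy3 -0.18, adjusted p = 0.00636, limma). Without pair 2 the unadjusted count was 25 and without pair 1 it was 11, and without pair 3, 4, 5 or 7 it was 0. With pair 2 left out, the dye balance term takes up pairs 6 and 7, so the ratio comes from the 4 dye-swapped pairs alone. Of the 171 log2 ratios, 73 were positive and 98 negative in the labelled direction of all pairs, with IL8 at 0.19. With each gene's own variance, the 95% confidence intervals of 170 genes lay within a 2-fold difference either way and those of 165 within 1.5-fold. The exception at 2-fold was IL8, whose fitted log2 ratio of 0.19 had an interval from -1.12 to 1.50. These intervals rest on normexp ratios, whose compression was checked by a spike for bright probes alone. With the lists tested by camera, camera with an estimated correlation, and fry, 0 of the 12 tested lists passed under any of these.

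**Figure D1:**
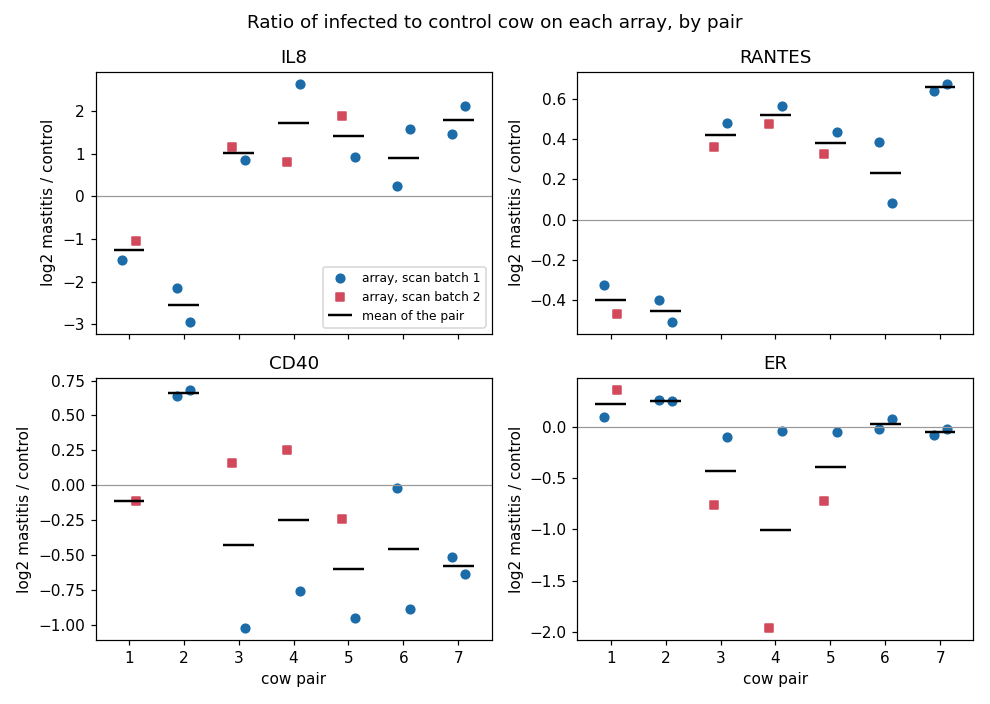
Log2 ratio of the infected to the control cow (vertical axis) on each array of the 7 cow pairs (horizontal axis) for IL8, RANTES, CD40 and ER; blue circles are arrays of scan batch 1, red squares arrays of scan batch 2 and black bars the mean of the pair. IL8 lies below 0 on both arrays of pairs 1 and 2 and above 0 on both arrays of the other 5 pairs.

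**Figure D2:**
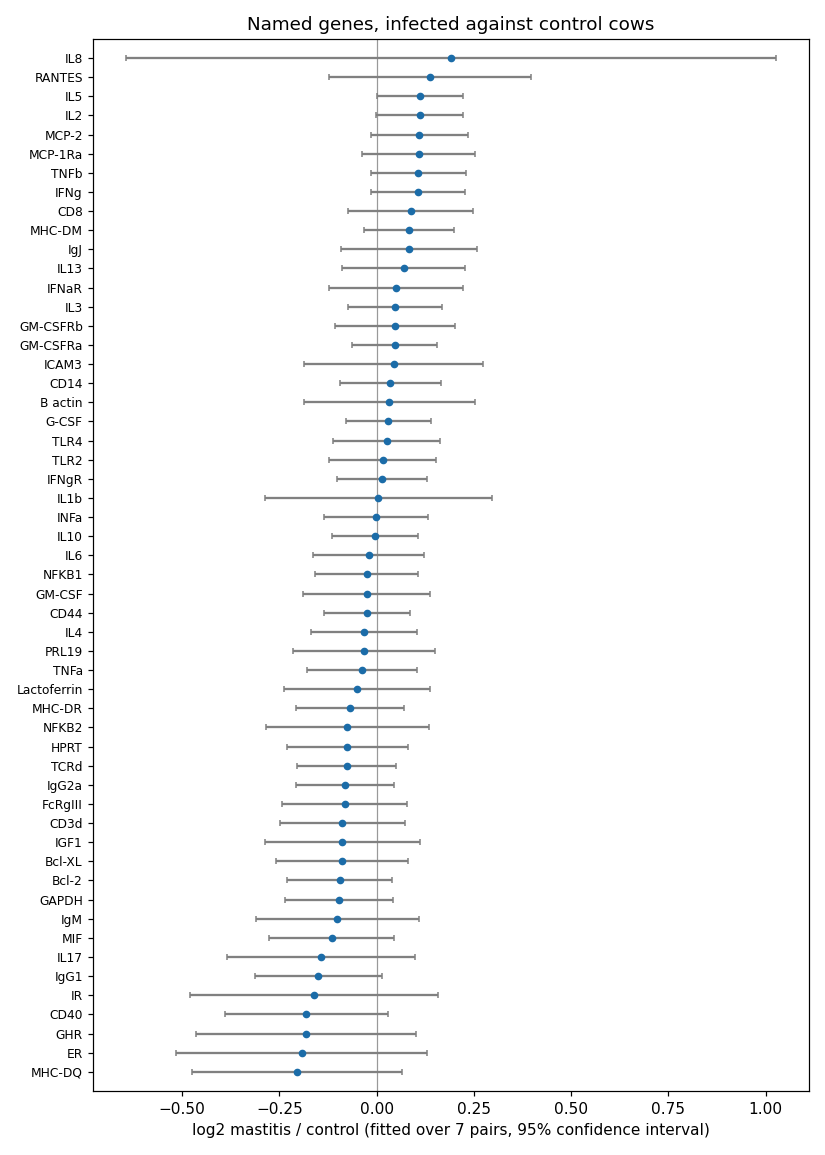
Fitted log2 ratio of infected to control cows (horizontal axis) for the named genes whose ratios are reported here (vertical axis), with 95% confidence intervals from limma over 7 pairs. IL8, at 0.19, has the widest interval, and the interval of IL5 alone lies to one side of 0.

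Among the 13 measured proinflammatory cytokines, 7 had a positive and 6 a negative log2 ratio, and 0 passed the test, also with p adjusted over the list alone. IFNg (IFNG), the main macrophage-activating cytokine, stood at 0.11 (SE 0.05) with 4 of 7 pairs above 0, and TNFb (LTA) at 0.11 with 5 of 7. Both probes were also brighter in Cy3 whichever cow it labelled (log2 Cy5/Cy3 -0.16 for each, adjusted p = 0.0149 and 0.0128, limma). The acute inflammatory cytokines lay nearer to 0, with TNFa (TNF) at -0.04 (SE 0.06), IL6 at -0.02 (SE 0.06) and IL1b (IL1B) at 0.00 (SE 0.13). Pair values of IL1b reached -0.84 in pair 2 and 0.69 in pair 4. IL17 (IL17A), which promotes neutrophil recruitment, was at -0.14 (SE 0.11) and MIF at -0.12 (SE 0.07). GM-CSF (CSF2), a growth factor of granulocytes and macrophages, was at -0.03 (SE 0.07). As a list, the proinflammatory cytokines gave an adjusted p of 0.577 (camera in limma), with 7 of 13 values positive.

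Of the 16 measured chemokines and chemokine receptors, 8 were positive and 8 negative, and 0 passed, also adjusted over the list alone (list adjusted p = 0.582, camera in limma). After IL8, the largest ratios were those of RANTES (CCL5), a chemokine for T cells and monocytes, at 0.14 (SE 0.12), MCP-2 (CCL8) at 0.11 (SE 0.06) and the receptor probe MCP-1Ra (CCR2) at 0.11 (SE 0.06). MCP-2 had a value on 9 arrays and was above background on 4 in each channel. MCP-1Ra was above background on 9 arrays in the infected channel and on 6 in the control channel. RANTES had the same division between pairs as IL8, at -0.40 in pair 1, -0.45 in pair 2 and between 0.23 and 0.66 in the other 5. The 8 regulatory and type 2 cytokines had 5 positive and 3 negative values, 0 of them past the test overall or adjusted over the list alone. Besides IL5, IL13 was at 0.07 (SE 0.07), IL3 at 0.05 (SE 0.05), IL4 at -0.03 (SE 0.06) and IL10, an anti-inflammatory cytokine, at -0.0035 (SE 0.05), and the list had an adjusted p of 0.577 (camera in limma).

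The sensors of bacterial products showed small ratios, and none of the 5 measured genes of pattern recognition and NF-kB passed, also adjusted over the list alone. TLR2, the receptor for lipoproteins of gram-positive bacteria, was at 0.02 (SE 0.06), TLR4, the lipopolysaccharide receptor, at 0.03 (SE 0.06), and their co-receptor CD14 at 0.04 (SE 0.06). The transcription factor subunits NFKB1 and NFKB2 were at -0.03 (SE 0.06) and -0.08 (SE 0.09), and the list gave an adjusted p of 0.802 (camera in limma). The list's test pointed upward and its median was 0.02, while its mean was -0.0047. The interferon system was represented by 3 probes, at 0.05 for the receptor IFNaR, 0.01 for IFNgR and -0.0023 for INFa, with 0 past the test, also adjusted over the list alone, and a list adjusted p of 0.598 (camera in limma).

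In the antigen presentation list, 9 of the 10 measured genes had negative values in the labelled direction. The class II genes MHC-DQ and MHC-DR were at -0.21 (SE 0.12) and -0.07 (SE 0.06), and CD40, a costimulatory receptor of antigen-presenting cells, at -0.18 (SE 0.09) with 6 of 7 pairs below 0. CD40 was brighter in Cy3 whichever cow it labelled (log2 Cy5/Cy3 -0.46, adjusted p = 0.00636, limma). Cy3 was the dye of the control cow on both arrays of pairs 6 and 7. The arrays of pairs 3 and 4 had opposite CD40 signs, and in pair 1 the CD40 value rests on 1 array. The count of pairs thus does not show agreement between cows. The MHC-DQ value rests on pair 1 (-0.92), whose arrays gave -0.28 and -1.55, and without that pair it was -0.08. CD40 was at -0.35 without pair 2. That value comes from the 4 dye-swapped pairs alone, since the dye balance term then takes up pairs 6 and 7. MHC-DM, which loads peptides on class II molecules, was the positive member at 0.08 (SE 0.05). None of the 10 genes passed, also adjusted over the list alone, and the list did not pass either, at an adjusted p of 0.577 (camera in limma), and an adjusted p of 0.62 with an estimated correlation. CD40 was above background on 5 of the 14 arrays in the infected channel and on 9 in the control channel.

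The endocrine and growth factor axis had 9 negative and 4 positive values among 13 measured genes, and 0 passed, also adjusted over the list alone (list adjusted p = 0.577, camera in limma). The estrogen receptor probe ER stood at -0.19 (SE 0.14), the growth hormone receptor GHR at -0.18 (SE 0.13), the insulin receptor IR at -0.16 (SE 0.14) and IGF1 at -0.09 (SE 0.09). ER, GHR and IR were below 0 in pairs 3, 4 and 5, with the lowest value for ER in pair 4, and above 0 in pairs 1 and 2. Without pair 2, ER was at -0.40, GHR at -0.36 and IR at -0.36, and within the first scan batch they were at 0.06, 0.05 and 0.08. The values without pair 2 come from the 4 dye-swapped pairs alone, since the dye balance term then takes up pairs 6 and 7. The median log2 Cy5/Cy3 ratio of the list was 0.311 to 0.993 on the 4 arrays of the second of 2 scan batches and -0.102 to 0.105 on the 10 arrays of the first. In the apoptosis list, the survival factors Bcl-2 and Bcl-XL were at -0.10 (SE 0.06) and -0.09 (SE 0.08). The probe of FasL was not above background on any array, and no ratio is given for it. Of the 8 apoptosis genes 0 passed, also adjusted over the list alone (list adjusted p = 0.582, camera in limma).

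No marker of the cell types that milk can hold passed the test between infected and control cows. Among 19 T cell and NK cell markers, 9 were positive and 10 negative, with IL2 at 0.11 (SE 0.05; 6 of 7 pairs above 0), CD8 at 0.09 (SE 0.07), CD3d at -0.09 (SE 0.07) and TCRd, a chain of the gamma-delta T cell receptor, at -0.08 (SE 0.06). The 2 arrays of IL2 had opposite signs in pairs 3 to 7. IL2 was also brighter in Cy3 whichever cow that dye labelled (log2 Cy5/Cy3 -0.18, adjusted p = 0.0128, limma). Among 7 B cell and plasma cell markers, 5 were negative, with the immunoglobulin probes IgG1 at -0.15 (SE 0.07), IgM at -0.10 (SE 0.09) and IgG2a at -0.08 (SE 0.06), and IgJ at 0.08 (SE 0.08). The 5 neutrophil and monocyte markers had 3 positive and 2 negative values, among them the Fc receptor FcRgIII at -0.08 (SE 0.07) and G-CSF (CSF3) at 0.03 (SE 0.05). The receptor chains GM-CSFRa and GM-CSFRb were both at 0.05, with SE 0.05 and 0.07. None of these genes passed, also adjusted over each list alone, and the 3 lists had adjusted p of 0.582, 0.577 and 0.602 (camera in limma). The T cell and NK cell list had a median of -0.0074 and a mean of 0.0042, and its test pointed upward. Lactoferrin (LTF), an iron-binding antibacterial protein of milk and of neutrophil granules and the 1 measured gene of the mammary epithelial list, was at -0.05 (SE 0.08). Of the adhesion list, CD44 was at -0.03 (SE 0.05) and ICAM3 at 0.04 (SE 0.10). The reference genes GAPDH, HPRT, PRL19 and B actin were at -0.10, -0.08, -0.03 and 0.03 (list adjusted p = 0.577, camera in limma), and 0 of these 7 genes passed, also adjusted over each list alone.

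The comparison of the 2 arrays of a pair asks how far the ratios repeat. For IL8 and RANTES both arrays of each pair had the same sign, and ER had 1 sign within each dye-swapped pair but different sizes, as in pair 4 with -1.96 and -0.04. CD40 had opposite signs on the arrays of pairs 3 and 4, with 0.25 and -0.76 in pair 4. The correlation of the turned log2 ratios across genes, which are not independent replicates, was r = 0.732 in pair 2 and 0.687 in pair 7, where dyes were not exchanged, but -0.166 in pair 6, also without an exchange. On array 1 of pair 6 normexp compressed the brightness range (ratio of the 90th to the 10th percentile 1.59 in Cy5 and 1.83 in Cy3). Whether this lowered the correlation was not tested. In the dye-swapped pairs 1, 3, 4 and 5 it was 0.181, 0.124, -0.04 and 0.245. The median over the 7 pairs was 0.181. Between pairs, the profiles of pairs 3 to 7 correlated with each other at r from 0.159 to 0.788, pairs 1 and 2 with each other at 0.225, and pairs 1 and 2 with the other 5 at r from -0.637 to -0.334. Unturned Cy5/Cy3 profiles of opposite dye orientation correlated positively in the first scan batch (median r 0.571, 21 of 21 array pairs above 0). Those of the same orientation in that batch had a median r of 0.425, with 22 of 24 above 0. Between scan batches, over both orientations together, the median r was -0.161, with 10 of 40 above 0.

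The dye comparison asks which genes were brighter in one dye whichever cow it labelled. In a fit of all 14 arrays with the pair as a random block, 29 of 171 genes differed between the dyes at an adjusted p under 0.05 (limma), with 12 brighter in Cy5 and 17 in Cy3. IgG1 was brighter in Cy5 by a log2 ratio of 0.34 (SE 0.06, adjusted p = 0.00429, limma), and CD40 was brighter in Cy3, with -0.46 (SE 0.09, adjusted p = 0.00636, limma). With a dye term for each scan batch, 17 genes passed for the first batch, 8 of them among the 29. The arrays were scanned in 2 batches of 10 and 4 arrays, and each dye-swapped pair had 1 array in each batch. The mean log2 Cy5/Cy3 ratio of IL8 was 1.64 ± 0.84 (SD, 10 arrays) in the first batch and -1.22 ± 0.46 (SD, 4 arrays) in the second, with all 10 arrays above 0 and all 4 below 0. That of ER was -0.09 ± 0.10 in the first and 0.95 ± 0.70 in the second, that of CD40 -0.68 ± 0.30 (9 arrays measured) and -0.07 ± 0.22, and that of IgG1 0.14 ± 0.15 and 0.66 ± 0.20. Within the first batch alone, the fitted mastitis to control ratio of IL8 was -0.30 and within the second 0.12, against 0.19 over both, and 0 genes passed in either batch (limma; 7 and 16 at an unadjusted p under 0.05). In a fit of the 14 arrays with a dye term for each batch, IL8 was at -0.26, against 0.35 with 1 dye term for both, and 0 genes passed in either fit (limma; 10 and 15 at an unadjusted p under 0.05). The second batch has 1 array with the infected cow in Cy5, whose spread is assumed to be that of the others.

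**Figure D3:**
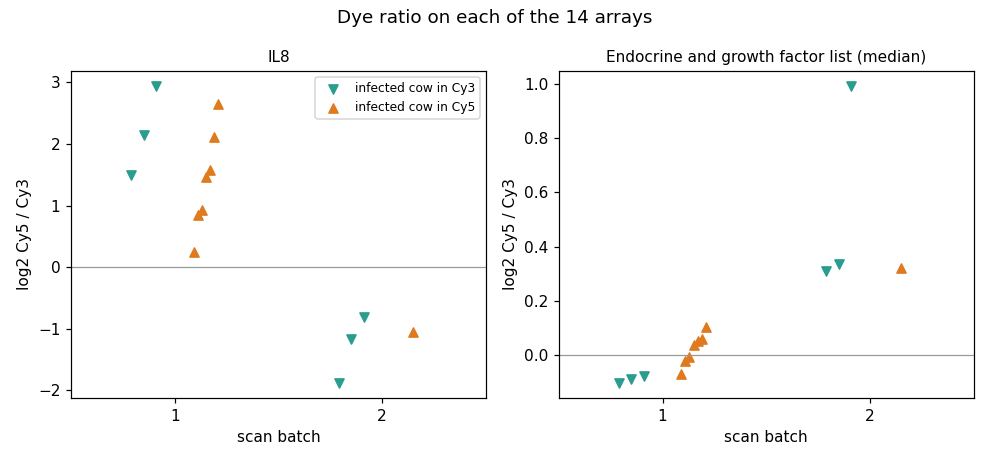
Log2 Cy5/Cy3 ratio (vertical axis) on each of the 14 arrays by scan batch (horizontal axis), for IL8 on the left and the median of the endocrine and growth factor list on the right; triangles pointing down have the infected cow in Cy3, triangles pointing up in Cy5. IL8 is above 0 on all 10 arrays of the first batch and below 0 on all 4 of the second, whichever dye the infected cow had.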

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

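The tests of the IL8 pattern and of sign patterns over the 7 pairs were chosen after the results were seen.

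In 3 of 56 named genes a single pair stood apart from the other 6, where chance alone marks about 1 gene in 20, or 2.8 here. CD40 was at a log2 ratio of 0.66 in pair 2, ICAM3, an adhesion molecule of leukocytes, at 0.68 in pair 2, and CD3d, a chain of the T cell receptor complex, at -0.45 in pair 1. The screen used pair means without the dye balance term, and pair 2 alone had the infected cow in Cy3 on both arrays. CD40 had log2 Cy5/Cy3 ratios of -0.64 and -0.68 there, against a mean of -0.68 ± 0.30 (SD) on 9 arrays of the first batch. Its value in pair 2 thus cannot be told apart from a dye bias of the probe. None of the 12 list medians had such a pair.

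The infected to control ratio of 29 genes differed between arrays of opposite dye orientation. Of 100 sign patterns of the 14 arrays, the real one included, 1 gave as many genes, with 12 the highest among the others. The draws turned each array independently. Real Cy5/Cy3 profiles correlated within the first scan batch (median r 0.571 between opposite orientations and 0.425 within the same one). Between batches, over both orientations together, the median was -0.161. The count thus lies above that of random independent signs, but chance is not excluded for this dye effect. The pattern that follows the scan batch gave 13.

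Control features outside the gene comparisons gave signal where the buffer spots had 0 of 56 spots above background in both channels. The feature NC4, named INS on the array, was above background in 54 of 56 spots and on all 14 arrays, at a median net Cy3 brightness of 987 against 444 for gene spots. NC1 and NC2 were above in 7 spots each and NC3 in 1 of 56. The DNA features DNA1 and DNA2 were above in 55 of 56 and 112 of 112 spots.

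With 0 genes and 0 lists past the threshold between infected and control cows, all 64 of the 64 sign patterns of the 7 pairs give as many whatever the data, so these counts say nothing about chance. Among the others, the highest number of genes was 30 and, under other patterns, the highest number of lists was 2. The 30 genes came with pairs 1 and 2 turned and again with pairs 1, 6 and 7 turned, which is the same fit, since the dye balance term then leaves the ratio to the dye-swapped pairs. As the highest of all patterns it was picked by its count, and nothing is concluded from it. Of the 63 other patterns, 4 gave at least 1 gene and the median was 0. Within each scan batch 0 genes passed (limma; 7 and 16 at an unadjusted p under 0.05), but the second has 1 array with the infected cow in Cy5, whose spread is assumed to be that of the others.

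IL8 lies below 0 in pairs 1 and 2 and above 0 in the other 5. The tables argue against a dye bias of the probe that is the same in both scan batches, since its mean Cy5/Cy3 ratio was 1.64 in the first batch and -1.225 in the second, both far from 0 against their spread. A dye bias that differs between scan batches could give the signs, which were as the batch predicts on 14 of 14 arrays. Infection labels reversed in pairs 1 and 2 could give them too, and the median correlation across genes of these pairs with the other 5 was -0.455. These explanations predict the same sign on all 14 arrays and cannot be told apart, because of how dyes and batches were assigned, and a true difference in IL8 between pairs of cows stays open, untested.

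Endocrine genes were brighter in Cy5 on the arrays of the second scan batch, with list medians of 0.311 to 0.993 against -0.102 to 0.105 in the first. Of 3 tests of its cause tried after it was seen, 1 set list medians against the spread of single genes and left a difference between cows undecided. The other 2 had outcomes that followed from the pattern itself, and no test result of the 3 is used. Infected over control, the list median in pair 4 was 0.051 (SD over genes 0.067) in the first batch and -0.993 (0.8) in the second. It was 0.039 (0.153) and -0.311 (0.25) in pair 5, -0.068 and -0.335 in pair 3, and 0.077 and 0.322 in pair 1. A difference between cows alone would give both arrays of a pair about the same median, apart from array noise. The signs were opposite in pairs 4 and 5, but the first-batch medians there were smaller than their SD over genes. The gap between the arrays also follows from the pattern itself, so nothing is concluded from it. A difference between cows, a dye bias, the scan batch and the array printing stay open, with no test used.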

How the results depend on the processing

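Of the alternatives, leaving out array 1 of pair 6, using the first layout's identifiers on all arrays, and, for the dye effect, a dye term of its own in each scan batch were chosen after seeing the data. Between infected and control cows, 0 genes and 0 lists passed in any of the 28 alternatives of the limma fit, with the lowest adjusted p of a gene at 0.057 (within the second scan batch) and of a list at 0.157. The number of genes at an unadjusted p under 0.05, 1 as reported, was 6 with plain background subtraction, 3 with the lower normexp offset, 3 with scaling between arrays, 2 with spots kept whatever their mark and 3 with robust and trended eBayes. It was 0 with the dimmest genes left out, a filter that also removes IL8, and 0 with spots above background. It was 15 with 14 arrays, a dye term and the pair as a random replicate block, 10 with a further dye term for the second scan batch, 15 in the dye-swapped pairs alone, 7 and 16 within the first and second scan batch, and 6 with the authors' value table. Without array 1 of pair 6 it was 3, and without each pair in turn it ranged from 0 to 25, with 25 without pair 2 and 11 without pair 1. Leaving out pair 2 also leaves the ratio to the 4 dye-swapped pairs, as the dye balance term then takes up pairs 6 and 7. Other causes of these differences were not tested. The share of positive log2 ratios was 42.7 percent and became 53.3 percent within the first scan batch.

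Of 1544 values of the 56 named genes under alternatives, 1533 moved by less than 1 SD over the pairs and 11 by more. For 18 named genes the sign held in all alternatives that gave a value, and for 38 it was the opposite in at least 1. IL8 ranged from -0.30 to 0.72 and was negative in 4 of 27. The dye effect was found in 30 genes with median centring, 27 of them shared, and in 17 for the first scan batch with a dye term of its own in each, 8 of them shared. The median correlation of the arrays of a pair was 0.222 with median centring and 0.006 among the genes brighter than the median. Signal over background left FasL, above background on no array, without a ratio.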

Other observations

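The genes below and the count of signs in each scan batch were chosen after the values were seen.

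Of genes that the naming rule left out, IL2R, the interleukin 2 receptor of activated T cells, NRAMP1 (SLC11A1), a metal transporter of the phagosome, and MHC-I varied most between pairs. The mean log2 ratio of IL2R was 0.06 ± 0.58 (SD, n = 7), with -1.03 in pair 2 and 0.57 in pair 7. NRAMP1 was at 0.18 ± 0.47 (SD, n = 7), below 0 in pairs 1 (-0.24) and 2 (-0.67) and between 0.21 and 0.61 in the other 5. MHC-I was at 0.02 ± 0.49 (SD, n = 7), with -1.04 in pair 1, where its arrays gave -0.18 and -1.90. The fitted log2 ratios, with the dye balance term, were -0.04 for IL2R, 0.13 for NRAMP1 and -0.02 for MHC-I, and none passed between infected and control cows (limma, adjusted p of 0.875, 0.821 and 0.959).

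Of 153 genes measured on all 14 arrays, 5 had a single Cy5/Cy3 sign throughout each scan batch, where 0.04 are expected by chance if arrays were independent. In 4 of them the sign was opposite between batches, namely IL8, RANTES (mean log2 0.45 and -0.41), NRAMP1 (0.49 and -0.33) and TAPA (-0.07 and 0.38), and in FcR2 it was the same. Across 168 genes, the mean Cy5/Cy3 ratios of the batches correlated at r = -0.224.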
